A study of Mus musculus with 19 samples.

How the data were processed

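RNA from mouse gastrocnemius was labelled with biotin and measured on Illumina bead arrays, per the labels' protocols. The deposited table gives the average signal intensity of each probe on each array, without background subtraction or normalization between arrays, per the file headers and the values. A detection p-value, which compares a probe with the negative control beads of its array, stands beside each signal, per the file headers. A further deposited table holds the authors' processed intensity values, which from their identical quantiles were quantile normalized on a linear scale without background subtraction. The scanner software, the handling of outlier beads and the chip of each array are not given in the sources used here.

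The groups were taken from the labels. Background was corrected with limma's nec function from the detection p-values (offset 16), values were quantile normalized and taken to log2 (limma 3.58.1, R 4.3.3). A probe was kept with a detection p-value under 0.05 on at least 3 arrays, which left 21083 of 45281 probes. For a gene with several probes, the probe with the highest mean was used, which left 14646 features. Gene names in the table were updated through a RefSeq table of assembly GRCm38.p6, used for names alone: 27400 probes matched by symbol, 8300 by a unique synonym, 9519 kept the table's name and 62 had no gene name. Of the features, 12241 had a RefSeq symbol, and the other 2405 were counted but not named. No coordinates are given, since the build behind the probes is not given in the sources used here.

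One linear model with a mean for each of 5 groups was fitted to all 19 arrays with limma (lmFit and eBayes, 14 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were ischemic against non-ischemic muscle under each oligonucleotide, anti-miR-210 against scramble with and without ischemia, the interaction, and each non-ischemic group against untreated muscle. Log2 fold changes carry the moderated standard error (SE) of this model. Gene lists with at least 5 measured members were tested with limma camera, 28 lists per comparison, with a preset correlation of 0.01 and again with the correlation estimated from the data. The lists, the tests and the rule for naming genes were fixed before the data were examined, apart from lists of hepatocyte, kidney tubule and circadian clock genes, which were added afterwards and not tested with camera. The hepatocyte list left out the liver genes whose values had been seen when it was made, and some of its members, such as Apoa2, were later named among the largest falls.

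Genes were named by this rule: among genes past the threshold with all arrays of one group beyond all arrays of the other, the 10 largest rises and 10 largest falls of each comparison (5 and 5 against untreated muscle), or all genes past the threshold where fewer than 20 passed, with no separation asked for the interaction. In each list described, up to 4 members with the largest change among those passing were named, or the member with the smallest p where none passed. Any measured member of the list of published miR-210 targets could be named in the oligonucleotide comparisons. Where no array of a group detected a gene, the fold is a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal among detected probes and the probe's own signal.

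The functions were tested on simulated arrays with the real genes' means and spreads. For the comparison of oligonucleotides in ischemic muscle, on 14646 genes, 13 of 67 genes changed by 0.5 on the log2 scale were recovered, 58 of 67 changed by 1 and 66 of 66 changed by 2, with 8 false calls. In the list test on simulated arrays, 1 of 28 lists was shifted by 0.5 and 1 was called. Simulated genes were drawn independently and without a difference in brightness between groups. The simulation therefore does not show how the tests behave with correlated genes or arrays of unequal brightness.

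Alternatives tried were normexp background correction with offset 50, no background correction, median scaling, cyclic loess, no detection filter, a filter at detection p-value under 0.01 on every array of a group, every probe as a feature, the mean of a gene's probes, the authors' processed values, a fit of only the groups compared, the replicate number as a block, array weights, eBayes with trend and robust options, and leaving out each array in turn. Added after seeing the data were scaling to the median of the probes detected on all arrays, brightness as a covariate, and fits without the dimmest pair of ischemic scramble arrays or without the pair of untreated arrays with most liver transcripts. A planned test of genes with a miR-210 seed site in the 3′ untranslated region was not run, since no untranslated region sequences were used here, and a chip block was not run, since no chip is named in the sources used here.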

Results

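Messenger RNA was measured in the gastrocnemius, the main calf muscle, of CD1 mice aged 2 months. MiR-210 is a microRNA that rises in cells short of oxygen, and the study asked what it does to gene expression in an ischemic limb. Mice received 12 mg/kg of a locked nucleic acid oligonucleotide of 15 nucleotides, either complementary to miR-210 (anti-miR-210) or of scrambled sequence, in 200 µl by tail vein. The femoral artery was dissected 2 days later, which deprives the hindlimb of blood, and the muscle was taken 3 days after that. The 19 arrays form 5 groups: 3 untreated, 4 non-ischemic scramble, 4 non-ischemic anti-miR-210, 4 ischemic scramble and 4 ischemic anti-miR-210. The labels number the replicates without saying that each came from a separate mouse, so the p-values measure only the spread between these samples. The level of miR-210 itself was not analysed here, so the arrays give no check that it was lowered.

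Between 14551 and 19152 of the 45281 probes were detected per array, and 14646 genes or other features were tested. The number of arrays per group limits the precision. Mean raw signal was 154 ± 28.6 (SD, n = 4) on the ischemic scramble arrays and 229 ± 37.7 (SD, n = 4) on the ischemic anti-miR-210 arrays, with ranges of 124 to 184 and 193 to 265. Brightness, the mean log2 raw signal of the 9955 probes detected on all arrays, was 0.71 higher in the ischemic anti-miR-210 group (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays allow). It was 0.51 lower in ischemic than in non-ischemic muscle under scramble (exact permutation p = 0.0286) and 0.37 higher under anti-miR-210 (exact permutation p = 0.114). The difference in detected probes was 2570 for ischemia under anti-miR-210 and -958 for non-ischemic scramble against untreated muscle (exact permutation p = 0.0286 for each). The first principal component held 69.6% of the variance and parted the 8 ischemic arrays from the other 11 arrays.

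**Figure D1:**
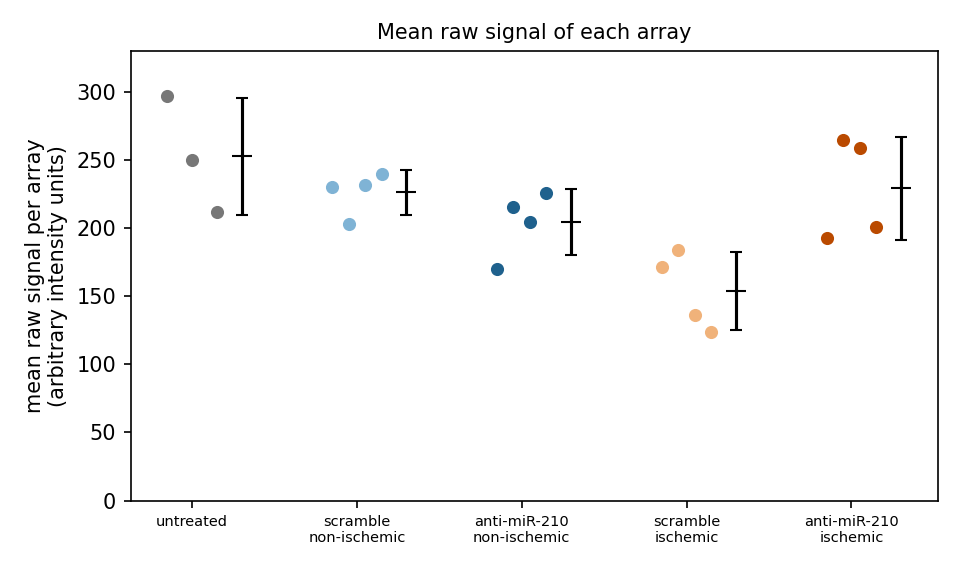
Mean raw signal of each array (y axis, intensity units) by group (x axis); points are arrays and the black marks give the mean and SD. The 4 ischemic scramble arrays lie between 124 and 184, below all 4 ischemic anti-miR-210 arrays, which lie between 193 and 265.

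The first comparison asked how muscle under the scramble oligonucleotide responded to 3 days of ischemia. Most measured genes of inflammation, macrophages and cell division rose, and most of energy metabolism fell. Spp1, which encodes the secreted protein osteopontin, rose from 4.99 ± 0.52 to 12.20 ± 0.21 on the log2 scale (SD, n = 4 in each group; log2 fold change 7.21, SE 0.32, adjusted p = 3.5e-12). Myl2, the slow-muscle and cardiac regulatory myosin light chain, had a log2 fold change of -4.25 (SE 0.62, adjusted p = 1.06e-05), and Slc2a4, the insulin-regulated glucose transporter, one of -3.81 (SE 0.26). In all, 7549 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 3946 higher and 3603 lower in ischemic muscle. Of 2875 called genes with several probes, 1635 had another probe that passed in the same direction. With every probe fitted, 155 genes had probes called in opposite directions.

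The other genes with the largest rises were Hp (haptoglobin, log2 fold change 6.09, SE 0.77), the chemokine Ccl7 (5.99, SE 0.54), the myeloid membrane gene Ms4a6d (5.57, SE 0.30), the adaptor gene Lat2 (5.55, SE 0.27) and the galectin gene Lgals3 (5.49, SE 0.29). The chemokine Ccl4 was not detected on any non-ischemic scramble array and was at least 37.1-fold higher with ischemia. The histone genes H2ac23, H2ac22 and H2ac7 had log2 fold changes of 6.32, 6.24 and 6.16. Their sequences are near-identical, so the probes are uncertain as to which copy they measured. The other largest falls were in Mettl21c (-5.09, SE 0.45), the mitochondrial regulator Perm1 (-4.13, SE 0.44), the collagen gene Col22a1 (-4.07, SE 0.33), the light chain gene Myl3 (-3.89, SE 0.48) and Yipf7 (-3.82, SE 0.23). The histone gene H4c8 (-3.85) and the unnamed-function genes 2310065F04Rik (-3.90) and 2310040G24Rik (-3.76) completed the set, H4c8 being one of several near-identical copies. Ccl7, Col22a1 and 2310065F04Rik were detected on 2 of the 4 arrays of their lower group, so the size of these changes is not exact.

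Macrophage, cytokine, neutrophil, interferon and cell cycle lists moved up, while those of T and NK cells (2 of 8 rose, camera adjusted p = 0.415) and B cells (1 of 7 rose and 1 fell, camera adjusted p = 0.772) did not pass, with the same counts adjusted over the list alone. Of 20 measured macrophage markers 17 rose and 3 did not pass, over all genes and adjusted over the list alone, with Gpnmb at a log2 fold change of 5.46 (SE 0.34) and the lysozyme gene Lyz2 at 4.72 (SE 0.46). Macrophage markers had a camera adjusted p = 6.58e-09, and an adjusted p = 0.105 with an estimated correlation. Of 19 inflammatory cytokines and chemokines 15 rose and 1 fell, with the same counts adjusted over the list alone. Cytokines and chemokines had a camera adjusted p = 2.38e-07, and an adjusted p = 0.0664 with an estimated correlation. Among 25 cell cycle genes 24 rose, also adjusted over the list alone, including the spindle gene Prc1 (5.47, SE 0.16; detected on 1 non-ischemic scramble array, so not exact), Birc5, which encodes survivin and was at least 17.1-fold higher, and the replication gene Mcm5 (4.13, SE 0.23). Cell cycle genes had a camera adjusted p = 7.77e-16, and an adjusted p = 0.0664 with an estimated correlation. Of 9 neutrophil markers 7 rose, also adjusted over the list alone, with S100a8 at 3.77 (SE 0.76) and Lcn2 at 3.75 (SE 0.28; detected on 2 of 4 non-ischemic scramble arrays, so not exact). Neutrophil markers had a camera adjusted p = 0.00429, and an adjusted p = 0.272 with an estimated correlation. Of 15 interferon response genes 6 rose, also adjusted over the list alone, led by Oasl2 (1.63, SE 0.42) and the immunoproteasome gene Psmb8 (1.42, SE 0.29). Interferon response genes had a camera adjusted p = 0.0383, and an adjusted p = 0.379 with an estimated correlation.

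Tissue groups rose as well. Fibroblast and extracellular matrix genes rose in 14 of 20 cases, 15 adjusted over the list alone, with Timp1, an inhibitor of matrix proteases, at 5.07 (SE 0.39), the collagen-crosslinking enzyme gene Lox at 3.49 (SE 0.37) and the protease gene Mmp14 at 3.33 (SE 0.22). Matrix genes had a camera adjusted p = 6.56e-05, and an adjusted p = 0.292 with an estimated correlation. Of 15 endothelial markers 9 rose, also adjusted over the list alone, with the tight junction gene Cldn5 at 2.78 (SE 0.28) and Egfl7 at 2.08 (SE 0.33). Endothelial markers had a camera adjusted p = 0.0222, and an adjusted p = 0.596 with an estimated correlation. Angiogenesis genes rose in 8 of 15 cases and fell in 2, with the same counts adjusted over the list alone. Angpt2, a regulator of vessel stability, was at 2.88 (SE 0.29) and Pdgfb at 1.86 (SE 0.27). Angiogenesis genes had a camera adjusted p = 0.0383, and an adjusted p = 0.368 with an estimated correlation. Apoptosis genes rose in 9 of 17 cases and fell in 1, with the same counts adjusted over the list alone, with the cell cycle inhibitor gene Cdkn1a at 2.88 (SE 0.38) and the apoptosome gene Apaf1 at 2.51 (SE 0.18). Apoptosis genes had a camera adjusted p = 0.00106, and an adjusted p = 0.0664 with an estimated correlation. Muscle regeneration genes rose in 7 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone). Those that rose included the fetal acetylcholine receptor subunit gene Chrng (3.78, SE 0.44), the myogenic transcription factor gene Myog (2.29, SE 0.23), Chrna1 (2.23, SE 0.26) and the embryonic light chain gene Myl4 (2.17, SE 0.57). The regeneration list did not pass (camera adjusted p = 0.0772).

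Transcripts of most measured energy metabolism genes fell. Levels are relative within each array of muscle RNA. A change within cells and a change in the mix of cells were not told apart, for these or other lists, under either oligonucleotide. All 34 measured genes of respiratory complex I fell, also adjusted over the list alone. Ndufb2 was at -3.40 (SE 0.25) and Ndufb9 at -2.81 (SE 0.27). Complex I genes had a camera adjusted p = 3.95e-16, and an adjusted p = 0.105 with an estimated correlation. In complexes II to V 32 of 34 fell and 1 rose, with the same counts adjusted over the list alone, with the muscle cytochrome oxidase subunit gene Cox7a1 at -2.88 (SE 0.26) and the ATP synthase gene Atp5pb at -2.57 (SE 0.27). Complexes II to V had a camera adjusted p = 1.52e-11, and an adjusted p = 0.106 with an estimated correlation. Of 15 genes on the tricarboxylic acid cycle list 14 fell and 1 rose, with the same counts adjusted over the list alone. Pdhb, a pyruvate dehydrogenase gene that acts just before the cycle, was at -2.81 (SE 0.33) and Idh3a at -2.79 (SE 0.26). Tricarboxylic acid cycle genes had a camera adjusted p = 2.13e-06, and an adjusted p = 0.123 with an estimated correlation. Fatty acid oxidation genes fell in 15 of 19 cases, also adjusted over the list alone, with the fatty acid carrier gene Fabp3 at -2.73 (SE 0.34) and Eci1 at -2.63 (SE 0.24). Fatty acid oxidation genes had a camera adjusted p = 8.37e-07, and an adjusted p = 0.152 with an estimated correlation. Genes on the glycolysis list fell in 14 of 17 cases, also adjusted over the list alone. Those that fell included the phosphorylase kinase genes Phkg1 (-3.51, SE 0.32) and Phka1 (-2.70, SE 0.27), which act in glycogen breakdown. Glycolysis genes had a camera adjusted p = 9.51e-06, and an adjusted p = 0.109 with an estimated correlation.

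Fibre lists moved down. Of 12 slow fibre genes 9 fell and 1 rose (10 and 1 adjusted over the list alone). Slow fibre genes had a camera adjusted p = 0.00154, and an adjusted p = 0.321 with an estimated correlation. Of 16 fast fibre genes 9 fell and 1 rose, with the same counts adjusted over the list alone, with the calcium store gene Casq1 at -3.69 (SE 0.39) and the myosin gene Myh2 at -3.25 (SE 0.57). Fast fibre genes had a camera adjusted p = 0.00479, and an adjusted p = 0.163 with an estimated correlation. Of 19 hypoxia response genes 6 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.88, direction down, while the median of 0.07 and the mean of 0.19 were positive). Lox, the glucose transporter gene Slc2a1 (2.16, SE 0.29) and Ndrg1 (1.66, SE 0.24) rose, while the oxygen sensor gene Egln1 fell (-2.33, SE 0.21; detected on 2 of 4 ischemic scramble arrays, so not exact). Vegfa, the main vessel growth factor gene, was chosen after its values were seen and fell (-1.57, SE 0.18, adjusted p = 9.18e-07). Of 20 published miR-210 target genes 4 rose and 8 fell (5 and 8 adjusted over the list alone), with Sdhd at -2.15 (SE 0.25), Cox10 at -1.55 (SE 0.15) and P4hb at 1.42 (SE 0.19; camera adjusted p = 0.504).

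Scaling changed the balance of calls but not the median direction of any list that shifted in this comparison. With median scaling the median of all genes lay at -0.11 and 2089 genes were called higher and 4190 lower. Scaled to the median of the probes detected on all arrays, a choice made after seeing the data, it lay at 0.47 with 5918 higher and 2779 lower.

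**Figure D2:**
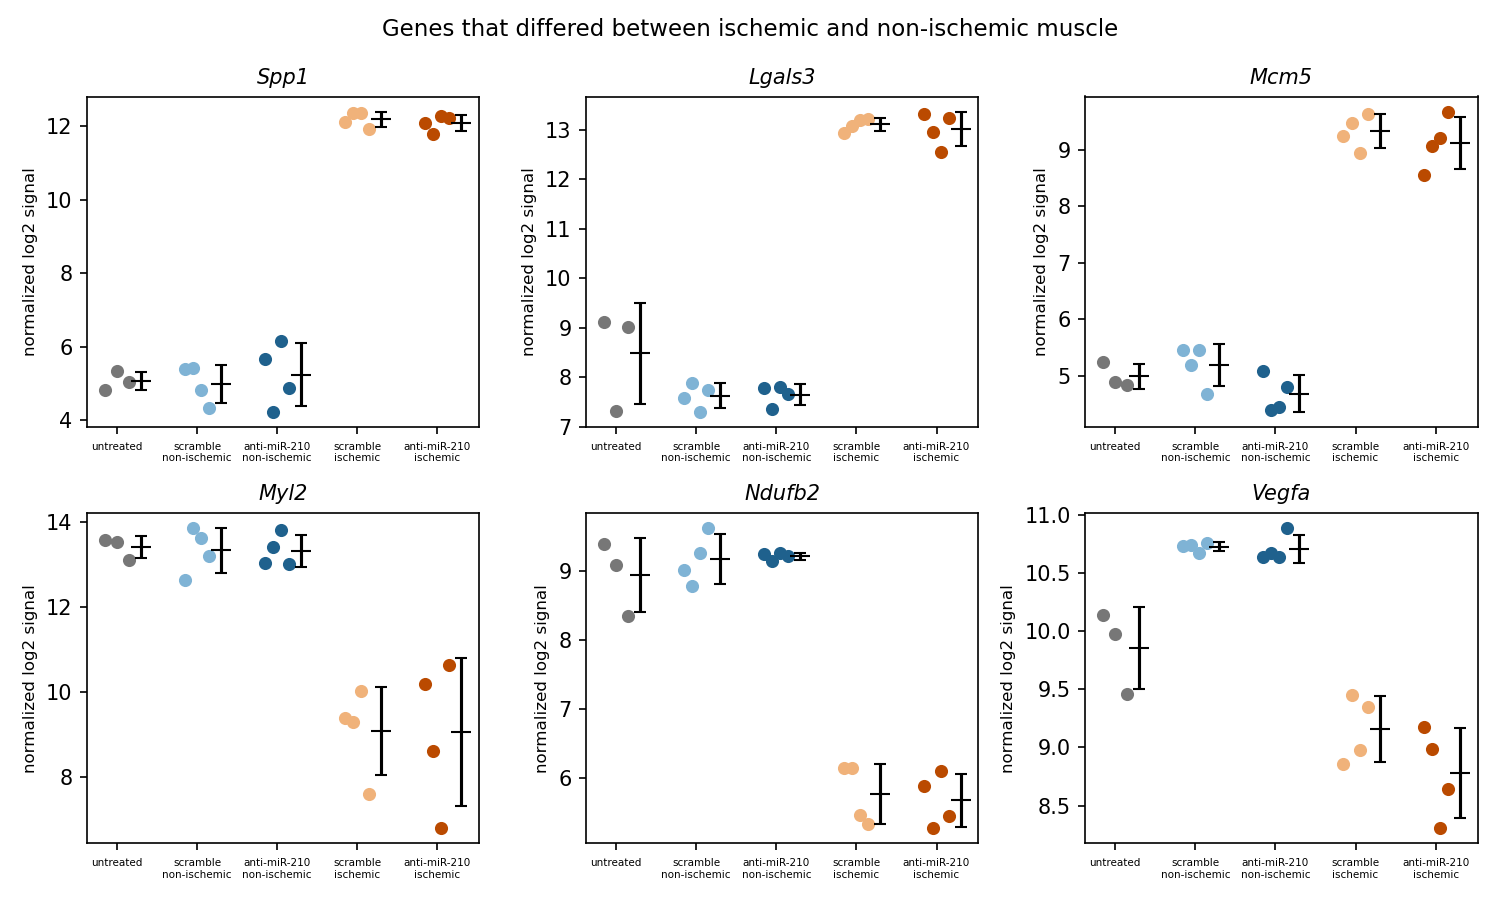
Normalized log2 signal (y axis) of 6 genes on each array by group (x axis); points are arrays and black marks give the mean and SD. Spp1, Lgals3 and Mcm5 were higher on all 8 ischemic arrays than on the other 11 arrays, and Myl2, Ndufb2 and Vegfa were lower; each panel has its own axis range.

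The second comparison asked the same of muscle under anti-miR-210. Most inflammatory, macrophage, matrix and cell cycle genes rose and most metabolic genes fell. Spp1 (log2 fold change 6.86, SE 0.32) and Gpnmb (6.64, SE 0.34) led the rises, followed by Lyz2 (5.61, SE 0.46), Timp1 (5.58, SE 0.39), Ms4a6d (5.54, SE 0.30) and the RNA-editing enzyme gene Apobec1 (5.53, SE 0.23). Arg1, the arginase found in some activated macrophages, was not detected on the non-ischemic anti-miR-210 arrays and was at least 42.4-fold higher. The near-identical histone genes H2ac23, H2ac7 and H2ac22 had log2 fold changes of 6.15, 6.15 and 5.79 and are uncertain as to copy, and H2ac22 was detected on 2 of 4 non-ischemic anti-miR-210 arrays. The largest falls were in Myl2 (-4.26, SE 0.62), Perm1 (-4.07, SE 0.44), Mettl21c (-4.03, SE 0.45), Myl3 (-3.96, SE 0.48) and Ndufb9 (-3.75, SE 0.27). Next came 2310065F04Rik (-3.66, SE 0.34), Ppp1r1a (-3.61, SE 0.31), Myoz2 (-3.60, SE 0.46), Phka1 (-3.60, SE 0.27) and Ndufb2 (-3.54, SE 0.25). Vegfa, again chosen after its values were seen, fell by 1.93 on the log2 scale (SE 0.18).

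All 20 macrophage markers, 19 of 20 fibroblast and matrix genes, 16 of 19 cytokines and chemokines, 22 of 25 cell cycle genes and 12 of 15 interferon response genes rose, with the same counts adjusted over the list alone. All 34 complex I genes fell, as did 32 of 34 in complexes II to V, 13 of 15 on the tricarboxylic acid cycle list and 15 of 17 on the glycolysis list (16 adjusted over the list alone). Of 16 fast fibre genes 8 fell, also adjusted over the list alone, and of 12 slow fibre genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). The fast and slow fibre lists had a camera adjusted p = 0.00518 and 0.00186, and 0.153 and 0.315 with an estimated correlation. In all, 7447 genes changed, 3880 higher and 3567 lower. Of 2804 called genes with several probes, 1692 had another probe that passed in the same direction, and 114 genes had probes called in opposite directions. Of 28 lists 14 shifted, 7 in each direction (limma camera). With an estimated correlation 4 lists passed, namely cell cycle, apoptosis, inflammatory cytokines and chemokines, and macrophage (adjusted p = 0.0487 for each), all of them up. The other 10 had an adjusted p between 0.101 and 0.315 with an estimated correlation. With median scaling 5438 genes were called higher and 1482 lower, the median of all genes lying at 0.26. Scaled to the median of the probes detected on all arrays it lay at -0.32, with 3149 higher and 4838 lower.

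**Figure D3:**
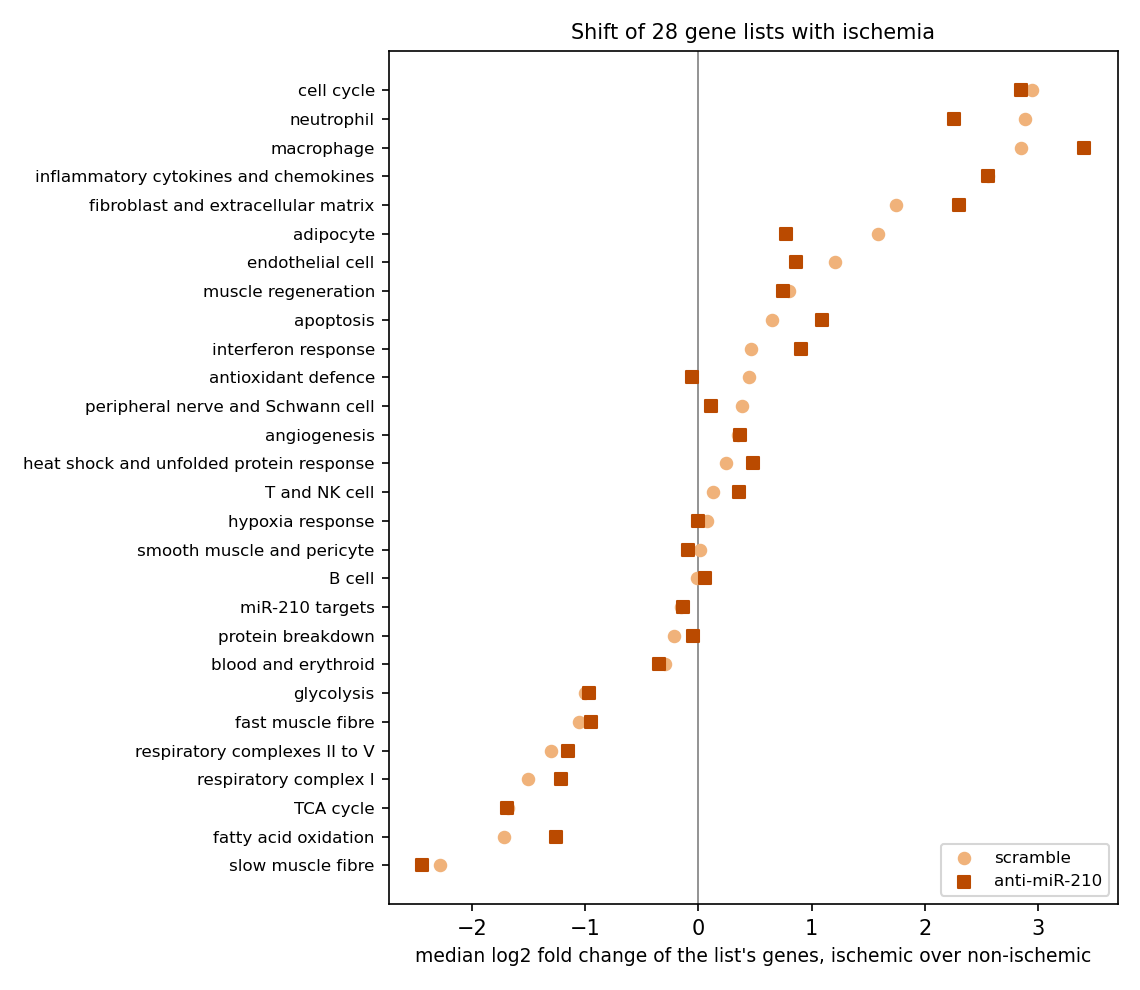
Median log2 fold change of each of 28 gene lists (y axis) between ischemic and non-ischemic muscle (x axis), for scramble (circles) and anti-miR-210 (squares). The macrophage list lies at 2.85 and 3.41 and respiratory complex I at -1.50 and -1.22; medians carry no error bar, and 16 and 14 lists passed the preset-correlation test and 0 and 4 with an estimated correlation.

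The ischemia responses under the oligonucleotides ran closely together. Across 14646 genes, which are not independent replicates, their log2 fold changes correlated with Pearson r = 0.944 and Spearman rho = 0.907, and these groups share no array. Of the 6191 genes called in both, 6185 had the same sign.

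The main question of the design was the effect of anti-miR-210 in ischemic muscle. Here 157 genes passed, 35 higher and 122 lower with anti-miR-210 (limma, adjusted p under 0.05). The largest rises were in the chitinase-like gene Chil4 (log2 fold change 1.45, SE 0.28, adjusted p = 0.0278), the deubiquitinase gene Usp2 (1.25, SE 0.25) and the protease gene Napsa (1.01, SE 0.17). They were followed by the potassium channel subunit gene Abcc9 (0.99, SE 0.22), Srd5a3 (0.99, SE 0.24), Svil (0.90, SE 0.20; detected on 2 of 4 ischemic scramble arrays, so not exact), Ly9 (0.88, SE 0.20), Rnaseh2c (0.87, SE 0.19), Cklf (0.83, SE 0.18) and Shisa5 (0.81, SE 0.18). The largest falls were in Sftpd, which encodes surfactant protein D (-1.99, SE 0.23, adjusted p = 0.000644), S100a13 (-1.68, SE 0.31) and Golga2 (-1.56, SE 0.36). Next came the cGMP-dependent kinase gene Prkg1 (-1.54, SE 0.22), Serpinb1a (-1.44, SE 0.29), Tex10 (-1.41, SE 0.25), Ptges3 (-1.32, SE 0.24), Nmd3 (-1.30, SE 0.28), Card14 (-1.27, SE 0.12, adjusted p = 4.17e-05) and the helicase gene Ddx3x (-1.25, SE 0.28).

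Published miR-210 targets did not move as a group: of 20 measured none rose and 1 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.369). The gene that fell was Stmn1, which encodes the microtubule regulator stathmin (-0.72, SE 0.12, adjusted p = 0.0128). Iscu, an iron-sulfur cluster scaffold gene, had a log2 fold change of 0.11 (SE 0.15), the cytochrome oxidase gene Ndufa4 of 0.08 (SE 0.19) and the phosphatase gene Ptpn1 of -0.61 (SE 0.15, adjusted p = 0.0593), and these did not pass. Some of the 20 targets lay near the floor, where a change is hard to see. Hoxa9 was detected on 0 of 4 ischemic scramble and 3 of 4 ischemic anti-miR-210 arrays. In that order Bdnf was detected on 1 and 2, Acvr1b on 2 and 3, and Aifm3 on 3 and 0. Macrophage markers shifted up, with C1qa (1.19, SE 0.28) and Itgam, at least 1.37-fold higher and not detected on the ischemic scramble arrays, passing among 20 (11 higher and 1 lower adjusted over the list alone). The macrophage list had a camera adjusted p = 5.75e-06, and an adjusted p = 0.533 with an estimated correlation. Its mean log2 fold change was 0.59, where the slope on brightness within the groups gave 0.55. Its mean level overlapped between the groups, at 7.89 to 8.77 on the ischemic scramble and 8.20 to 9.18 on the ischemic anti-miR-210 arrays. Fibroblast and matrix genes shifted up with none of 20 passing (2 higher adjusted over the list alone), Fn1 standing at 1.59 (SE 0.41, adjusted p = 0.0698). Fibroblast and matrix genes had a camera adjusted p = 5.75e-06, and an adjusted p = 0.676 with an estimated correlation. Their mean level was 10.49 and 10.21 on ischemic anti-miR-210 replicates 1 and 2 but 9.36 and 9.38 on replicates 3 and 4, near the 9.06 to 9.39 of the ischemic scramble arrays. Their mean log2 fold change was 0.62, against -0.07 from the brightness slope. Interferon response genes shifted up, Irf9 rising (0.62, SE 0.15) among 15 (3 higher adjusted over the list alone). The interferon list had a camera adjusted p = 0.000186, and an adjusted p = 0.533 with an estimated correlation, and a mean of 0.42 against -0.04 from the brightness slope. The mean level of the interferon list overlapped too, at 5.50 to 6.18 on the ischemic scramble and 5.88 to 6.41 on the ischemic anti-miR-210 arrays.

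Endothelial markers shifted down with none of 15 passing over all genes or adjusted over the list alone, Robo4 standing at -0.67 (SE 0.24). Endothelial genes had a camera adjusted p = 0.0105, and an adjusted p = 0.864 with an estimated correlation. Their mean level overlapped between the groups, at 7.78 to 8.59 on the ischemic scramble arrays and 7.56 to 8.67 on the ischemic anti-miR-210 arrays. The highest was ischemic anti-miR-210 replicate 4. Their mean log2 fold change was -0.36, and the brightness slope gave -0.49. With median scaling their median was positive (0.53), below the median of all genes (0.60), and the list did not pass (adjusted p = 0.793). Outside the lists that shifted, the spindle gene Nusap1 fell (-0.66, SE 0.13) as the 1 cell cycle gene of 25 (2 fell adjusted over the list alone). The neutrophil chemokine gene Cxcl2 fell (-1.61, SE 0.35) as the 1 of 19 cytokines and chemokines (3 rose and 3 fell adjusted over the list alone). Uqcrb was the 1 of 34 genes of complexes II to V that fell (-1.32, SE 0.28; 2 adjusted over the list alone). Unlike the 32 of 34 that fell with ischemia, Uqcrb was higher in ischemic muscle. Its mean went from 5.95 to 8.02 under scramble and from 6.00 to 6.69 under anti-miR-210. Tnfrsf10b was the 1 of 17 apoptosis genes that fell (-1.24, SE 0.24) and Abcc9 the 1 of 12 smooth muscle and pericyte genes that rose, with the same counts adjusted over the list alone. Members that did not pass were Egln3 of the hypoxia list (-0.72, SE 0.26), Des of the regeneration list (-0.28, SE 0.13) and Ndufa2 of complex I (0.33, SE 0.11). Brightness differed between these groups as given above, and 112 of the 122 lower and 28 of the 35 higher genes followed brightness within the groups in the direction of their difference, as did 9907 of all 14646 features. Rn18s, an 18S ribosomal RNA probe looked at after the data were seen, was 12.21 to 12.84 on the ischemic scramble arrays, below all ischemic anti-miR-210 arrays (13.04 to 13.64), though it did not pass the threshold in the limma fit.

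The count of 157 rested on the arrays and settings used. No gene passed when only the ischemic groups entered the limma fit or when brightness was a covariate, and 10 passed without the dimmest pair of ischemic scramble arrays. The full fit shares 1 spread over all groups, and the ischemic arrays varied more along the third principal component. Ischemic scramble and anti-miR-210 arrays ran from -35.06 to 2.24 and -12.44 to 39.62, the non-ischemic ones from -9.66 to -1.66 and -1.03 to 6.26. The SE of these genes may therefore understate the spread within the ischemic groups. With the groups as given, 2344 genes had an unadjusted p under 0.05. Median scaling called 6965 genes higher and 46 lower, with the median of all genes at 0.60. Scaling to the median of the probes detected on all arrays called 175 higher and 4852 lower, with that median at -0.37, and cyclic loess 35 higher and 56 lower. Of the 35 splits of the 8 arrays 3 gave as many genes, the highest 1271, so chance was not excluded. Apart from the real split, these kept 3 of 4 arrays of each group together. Of the 18 splits that mix the groups evenly 0 gave as many (highest 63). Without ischemic scramble replicate 1, 2, 3 or 4 the count was 65, 323, 22 or 22, and without ischemic anti-miR-210 replicate 2, 3 or 4 it was 17, 18 or 1201. The number of shifted lists was 4, and 7 without ischemic anti-miR-210 replicate 4. All 4 arrays of one group lay beyond all 4 of the other for 787 of the features, or for 110 of those called, where chance gives 2.86% of features. Of 49 called genes with several probes, 2 had another probe that passed in the same direction.

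The interaction tested whether the effect of ischemia differed between the oligonucleotides. The response of 3 genes was lower with anti-miR-210: Card14 (log2 difference -1.26, SE 0.17, adjusted p = 0.00855), Sftpd (-2.17, SE 0.33, adjusted p = 0.0174) and the tRNA methyltransferase subunit gene Trmt6 (-1.36, SE 0.21, adjusted p = 0.0174). Card14 was 4.33 ± 0.12 and 6.11 ± 0.17 without and with ischemia under scramble and 4.32 ± 0.11 and 4.84 ± 0.12 under anti-miR-210 (log2, SD, n = 4), and no non-ischemic injected array detected it. Sftpd was detected on 0 of 4 non-ischemic scramble and 1 of 4 non-ischemic anti-miR-210 arrays. The differences of Card14 and Sftpd thus rest on the ischemic groups and their size is not exact. Trmt6 went from 5.14 ± 0.20 to 5.82 ± 0.28 with ischemia under scramble and from 5.64 ± 0.14 to 4.95 ± 0.20 under anti-miR-210 (log2, SD, n = 4). Part of its difference therefore lies in the non-ischemic groups. Macrophage, fibroblast and matrix, and interferon response lists shifted up, with no member passing over all genes (camera adjusted p = 3.92e-05, 6.78e-07 and 0.0133); with an estimated correlation none passed (adjusted p = 0.751, 0.751 and 0.872). Adjusted over the list alone, 1 fibroblast and matrix gene and no macrophage or interferon gene passed.

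At an unadjusted p under 0.05, 1197 genes differed. The count of 3 became 0 with the replicate block or with brightness as a covariate and 1 with only the compared groups; median scaling called 4732 higher and 10 lower, and scaling to the median of the probes detected on all arrays 33 higher and 2875 lower. The median of all genes then lay at 0.74 and -0.41. The gene count was 1 without non-ischemic scramble replicate 1, 2 or 4, non-ischemic anti-miR-210 replicate 2 or 3 or ischemic anti-miR-210 replicate 2, and it was 10, 5 and 61 without ischemic scramble replicate 2, ischemic anti-miR-210 replicate 1 and ischemic anti-miR-210 replicate 4. The 3 lists became 6 without ischemic scramble replicate 2 or ischemic anti-miR-210 replicate 4.

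In non-ischemic muscle the comparison of anti-miR-210 with scramble gave 1 gene. Ap1b1, a subunit of a vesicle coat adaptor, was 9.09 ± 0.23 with scramble and 7.69 ± 0.34 with anti-miR-210 (log2, SD, n = 4; log2 fold change -1.41, SE 0.18, adjusted p = 0.00414). None of the 20 published miR-210 targets passed over all genes or adjusted over the list alone (camera adjusted p = 0.989), with Iscu at 0.15 (SE 0.15), Ndufa4 at 0.03 (SE 0.19) and Ptpn1 at -0.04 (SE 0.15). Stmn1, Aifm3 and Cpeb2 were not detected in either group. No list shifted with limma camera, 3 of 28 having an unadjusted p under 0.05, and 949 genes had an unadjusted p under 0.05. The gene count was 0 with median scaling or with only the compared groups, 8 with no filter and 7 with array weights, and 2 without non-ischemic scramble replicate 2 or non-ischemic anti-miR-210 replicate 4. The list count was 1 without non-ischemic scramble replicate 4 or non-ischemic anti-miR-210 replicate 1 or 3, and 2 without non-ischemic anti-miR-210 replicate 4. In ischemic muscle Ap1b1 was also lower with anti-miR-210, at 9.29 ± 0.25 against 10.33 ± 0.05 with scramble (log2, SD, n = 4). Its levels there did not overlap, at 9.06 to 9.56 and 10.28 to 10.39. Brightness also differed between the ischemic groups, as given above.

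The injected non-ischemic groups were also compared with untreated muscle. Their labels carry the same times of injection and dissection as the ischemic groups, which points to mice with an operated limb. The labels do not say outright from which limb this muscle came. Liver-type transcripts were lower on most injected non-ischemic arrays: Mup3 (log2 fold change -6.48, SE 1.12), Apoa2 (-6.46, SE 1.00), Apoa1 (-6.10, SE 0.91), Ttr (-6.04, SE 0.87) and Serpina1b (-5.85, SE 0.97) had the largest falls under scramble. Apoa2 was 12.21 ± 1.57 (log2, SD, n = 3) on the untreated arrays and 5.75 ± 2.97 (n = 4) on the non-ischemic scramble arrays. On non-ischemic scramble replicate 1 Mup3 was 11.07 and Apoa2 10.20, near untreated replicate 1 (11.08 and 10.50), while the other 3 arrays did not detect them (4.26 to 4.34 and 4.20 to 4.36), so these fold changes average unlike arrays and are not exact. Without non-ischemic scramble replicate 1 the log2 fold change of Mup3, scramble non-ischemic versus untreated, was -8.16. The largest rises were in the dynactin subunit gene Dctn1, which no untreated array detected and which was at least 5.51-fold higher, H2-T10 (2.60, SE 0.58; detected on 2 of 3 untreated arrays, so not exact), the stress-induced mTOR regulator gene Ddit4 (2.25, SE 0.53), Slc25a25 (2.19, SE 0.31) and the kinase gene Camk2a (1.79, SE 0.29). In all 422 genes changed, 152 higher and 270 lower. Of 22 measured hepatocyte genes, a list made after liver transcripts were seen to differ, 19 fell under scramble and 21 under anti-miR-210 (22 in each adjusted over the list alone). The untreated arrays differed among themselves in these genes, and without the pair with most liver transcripts 8 genes passed under scramble and 12 under anti-miR-210.

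Fatty acid oxidation and macrophage lists were shifted down against untreated muscle. Acaa2 was the 1 fatty acid oxidation gene of 19 that fell (-1.85, SE 0.35, 1 adjusted over the list alone). Fatty acid oxidation had a camera adjusted p = 0.0226, and an adjusted p = 0.986 with an estimated correlation. No macrophage marker passed over all genes and 1 of 20 adjusted over the list alone, Gpnmb standing at -1.38 (SE 0.37). Macrophage genes had a camera adjusted p = 0.00234, and an adjusted p = 0.86 with an estimated correlation. The untreated arrays also differed in other ways: Rn18s was 10.78 to 11.07 there and 12.95 to 13.82 on the injected non-ischemic arrays. On untreated replicates 1, 2 and 3 the hepatocyte mean was 6.71, 8.51 and 10.49, the fatty acid oxidation mean 10.03, 9.95 and 9.62, and the macrophage mean 5.93, 5.58 and 5.92. The Mup genes are near-identical and their probes uncertain as to copy, and H2-T10 also belongs to a family of similar genes. Not all injected arrays shared the rise of H2-T10. On non-ischemic anti-miR-210 replicates 1, 2, 3 and 4 it was 4.289, 4.185, 7.077 and 6.635. Without untreated replicate 3 the count was 188, and without non-ischemic scramble replicates 2, 3 or 4 it was 208, 226 or 262. It was 2060 with array weights and 109 with only the compared groups. Median scaling called 22 genes higher and 306 lower, with the median of all genes at -0.07. The 2 shifted lists became 0 without untreated replicate 1 and 1 without untreated replicate 2 or non-ischemic scramble replicate 2.

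Under anti-miR-210 the comparison with untreated muscle gave 839 genes, 385 higher and 454 lower. Ddit4 (3.29, SE 0.53), Dctn1 (at least 5.14-fold), Slc25a25 (2.24, SE 0.31), the actin-binding gene Xirp1 (1.97, SE 0.39) and Camk2a (1.97, SE 0.29) had the largest rises. Mup2 (-8.36, SE 1.45), Apoa2 (at least 198-fold lower), Mup3 (-7.79, SE 1.12), Mup1 (-7.27, SE 0.95) and Ttr (at least 128-fold lower) had the largest falls. Mup2 was detected on 2 and Mup3 and Mup1 on 1 of the 4 non-ischemic anti-miR-210 arrays, so the size of their falls is not exact. The macrophage list was shifted down, with 1 of 20 markers passing, also adjusted over the list alone. Macrophage genes as a list had a camera adjusted p = 0.0113, and an adjusted p = 0.969 with an estimated correlation. The count was 351 without untreated replicate 3, 545 without non-ischemic anti-miR-210 replicate 2, 2562 with array weights and 179 with only the compared groups, and median scaling called 18 genes higher and 748 lower. The median of all genes lay at -0.17 with median scaling and at 0.18 with scaling to the median of the probes detected on all arrays.

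**Figure D4:**
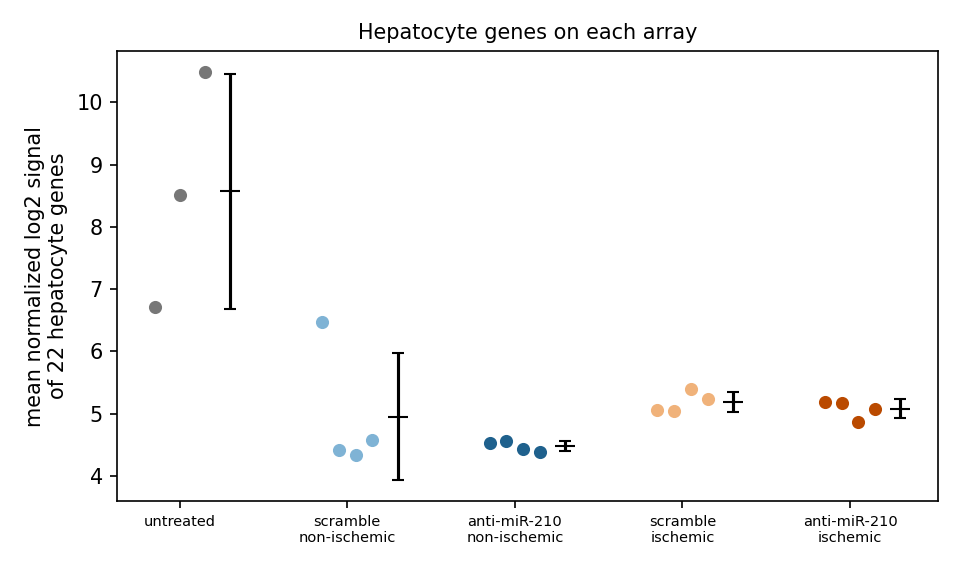
Mean normalized log2 signal of 22 hepatocyte genes (y axis) on each array by group (x axis); points are arrays and black marks give the mean and SD. The 3 untreated arrays lie at 6.71, 8.51 and 10.49 and non-ischemic scramble replicate 1 at 6.48, above the other non-ischemic arrays.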

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

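Chosen only after the result was seen were the brightness slope tests, brightness as a covariate, scaling to the median of the probes detected on all arrays, the test of an effect of the injection, the hepatocyte, kidney and clock lists with their tests, and Vegfa. In 592 groups of 4 arrays, over 148 values, 50 values lay further from the other 3 arrays of their group than Dixon's 95% critical ratio allows. Chance gives about 1 in 20 groups, so single entries carry little weight. All values here are normalized log2 levels, and the cause of single values was not tested.

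Liver transcripts made up the clearest set. On non-ischemic scramble replicate 1, Mup3 stood at 11.07, Apoa2 at 10.2, Apoa1 at 8.95, Ttr at 9.37, Serpina1b at 9.76, Mup2 at 12.67 and Mup1 at 9.36, and no other array of that group exceeded 4.83 in any of them. On non-ischemic anti-miR-210 replicate 1, Mup3 stood at 5.84, Apoa2 at 4.51, Apoa1 at 4.85, Mup2 at 7.52 and Mup1 at 4.87, where the others reached at most 4.70. Arg1 on non-ischemic scramble replicate 1 (5.49 against 4.18 to 4.38) and Itgam on non-ischemic scramble replicate 3 (4.57 against 4.19 to 4.21) lay near the floor.

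Among ischemic arrays, anti-miR-210 replicate 3 had a Ccl7 level of 7.34 against 10.54 to 10.87 in the others, an Ndufa2 level of 11.78, an apoptosis list mean of 6.89 and a Schwann cell list mean of 5.29. Anti-miR-210 replicate 4 stood apart in H2ac23 (13.55), H2ac22 (11.09), Ly9 (6.77), Angpt2 (9.60) and the heat shock list mean (8.22). Anti-miR-210 replicate 1 did so in Slc25a25 (6.78), the miR-210 target list mean (6.86) and the B cell list mean (5.93). Scramble replicate 4 had low means for glycolysis (10.09) and fatty acid oxidation (7.75), a low Fabp3 level (8.18) and a high Ccl4 level (10.27). Scramble replicate 3 was low in the cell cycle list mean (7.08) and in Fn1 (6.63), scramble replicate 2 in H2ac7 (12.73), and scramble replicate 1 in Ptges3 (7.58). Ms4a6d was high on scramble replicate 2 (11.84).

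Among non-ischemic arrays, anti-miR-210 replicate 3 was high in Myl3 (13.48) and in the slow fibre list mean (11.17), and scramble replicate 1 was low in the latter (9.63). Anti-miR-210 replicate 2 was low in Timp1 (4.85 against 6.55 to 6.65), Mmp14 (6.38), H4c8 (9.20) and the cytokine and chemokine list mean (4.78). Anti-miR-210 replicate 1 was high in Myh2 (13.09) and in the Schwann cell list mean (6.49), and anti-miR-210 replicate 4 in Cox10 (10.72) and Vegfa (10.89). Scramble replicate 4 was high in Myh2 (12.8) and low in Robo4 (7.88), scramble replicate 3 was low in Ndrg1 (6.46), and scramble replicate 2 had the lowest brightness of its group (8.10 against 8.31 to 8.34).

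The effect of ischemia differed between the oligonucleotides, by the interaction term, for Card14 (log2 difference -1.26), Sftpd (-2.17) and Trmt6 (-1.36). Card14 and Sftpd lay near the floor in non-ischemic muscle, so the size of their differences is not exact. The effect of ischemia also differed for the interferon response list (median 0.28), the macrophage list (0.83) and the fibroblast and matrix list (0.86), none of which passed with an estimated correlation. None of the genes passed with the replicate block or with brightness as a covariate. As many genes came from 8 of 100 splits of the arrays and as many lists from 81 of 100, so chance stays open.

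The 157 genes that differed between the oligonucleotides in ischemic muscle lay along a difference in array brightness. The slope on brightness within the groups gave a median share of 0.508 of the difference of the lower genes (0.447 to 0.68 with each array left out in turn) and 0.355 of that of the higher genes (0.147 to 0.538). Brightness as a covariate took the median log2 difference from -0.96 to -0.69 (median SE 0.20 to 0.28) and from 0.77 to 0.66 (median SE 0.17 to 0.24) and ended every call, by a smaller fold and a larger SE, so brightness and the oligonucleotide cannot be told apart for these genes, because the groups differ in both. Quantile normalization as the whole cause is argued against for the higher genes, since a share of 0.743 (26 of 35) passed after scaling to the median of the probes detected on all arrays, although 18 of 35 passed with cyclic loess, all 35 with the same sign. For the lower genes that share was 1, past the bound set against this explanation, but the scaling itself called 4852 genes lower, so it decides nothing, and 48 of 122 passed with cyclic loess (121 with the same sign) and 33 with median scaling, so quantile normalization and an effect of anti-miR-210 both stay open.

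Liver RNA may have reached the untreated samples and non-ischemic scramble replicate 1. Over 22 measured of 30 hepatocyte genes, a list made after other liver transcripts were seen to differ, the log2 ratio of untreated replicate 2 to replicate 3 had an interquartile range of 0.764 around -2.05, as a single source would give, while it was 1.20 for untreated replicate 1 and 1.34 for non-ischemic scramble replicate 1. Apoa1 and Ttr, abundant liver genes seen before and not in the list, reached 13.53 and 12.89 on untreated replicate 3, and 3 of the 22 genes were also detected on at least 3 of 4 non-ischemic anti-miR-210 arrays; the list holds Apoa2 and Arg1, named in the report, and Arg1 is also a macrophage gene. Kidney RNA stays open, since the median excess of 0.0583 on untreated replicate 3 rests on only 3 measured of 13 kidney tubule genes, and so does an effect of the injection, since the excess of 1.89 of non-ischemic scramble replicate 1 over the other injected non-ischemic arrays is 1 library. No biological source within the muscle was tested.

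Time of day at collection could also differ between untreated and injected muscle. The positive arm of the circadian clock lay 0.503 above the negative arm (mean log2 fold change) in the scramble comparison and 0.52 in the anti-miR-210 comparison. These lie just past a bound set before they were computed, but after the differences from untreated muscle were seen. The result rests on Arntl, without which the differences were 0.20 and 0.25, and 3 of 6 positive and 10 of 10 negative members were measured. Handling, injection, surgery on the other limb and the days between collections stay open, untested.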

How the results depend on the processing

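Scaling to the median of the probes detected on all arrays, brightness as a covariate, and the fits without a pair of arrays were chosen only after the result was seen. Array number and signal over background limit these results, and the cause of a change was not tested unless a fit's construction gives it. The gene counts of both ischemia comparisons stayed within 1.5 times under every alternative run. Of 144 values of named genes, 119 kept direction and side of the threshold with median scaling, 128 with cyclic loess, 130 with the mean of a gene's probes, 137 with normexp or the authors' values and 106 with only the groups compared, where 38 no longer passed. The last fit has fewer arrays behind the spread and takes it from the groups compared alone. With each array left out in turn 1005 of 1154 values kept direction and side of the threshold.

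For anti-miR-210 against scramble in ischemic muscle, the 157 genes became 7011 with median scaling, 91 with cyclic loess, 56 with no filter, 553 with array weights, 5027 with scaling to the median of the probes detected on all arrays and 10 without the dimmest pair of ischemic scramble arrays. No gene, or 0, passed with only the groups compared or with brightness as a covariate. The 4 lists became 0 with an estimated correlation, 10 with the probes-detected scaling and 12 with brightness as a covariate. Reversed with median scaling were Robo4 (0.35), Egln3 (0.34), Des (0.48), Nusap1 (0.37) and Ptpn1 (0.31), by construction, since that scaling took the median of all genes to 0.60. Ndufa4, not past the threshold, went to -0.034 with cyclic loess and, within a range of -0.12 to 0.20 with each array left out in turn, to -0.01, -0.04 and -0.12 without ischemic scramble replicate 3, ischemic scramble replicate 4 and ischemic anti-miR-210 replicate 3.

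For the interaction, the 3 genes became 4742 with median scaling, 2908 with the probes-detected scaling, 1 with only the groups compared, 9 with array weights, 5 with trend and robust options and 0 with brightness as a covariate. Its 3 lists became 5 with cyclic loess or the probes-detected scaling, 0 with an estimated correlation and 10 with brightness as a covariate. In non-ischemic muscle the 1 gene between oligonucleotides became 0 with median scaling or only the groups compared, 8 with no filter, 2 with the stricter filter, 5 with the mean of probes, 7 with array weights and 3 with trend and robust options. Its 0 lists became 1 with normexp, no background correction, cyclic loess, the stricter filter, the mean of probes, the authors' values or the probes-detected scaling, and 3 with only the groups compared or brightness as a covariate.

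Against untreated muscle, the 422 genes under scramble became 275 with no background correction, 221 with no filter, 109 with only the groups compared, 2060 with array weights and 8 without the pair of untreated arrays with most liver transcripts. The 2 lists became 1 with no background correction, median scaling, the stricter filter, array weights or brightness as a covariate, 0 with an estimated correlation and 4 without that pair. The 839 genes under anti-miR-210 became 179 with only the groups compared, 2562 with array weights, 506 with the probes-detected scaling and 12 without that pair, where the lone untreated array is assumed to vary like the other groups. The ischemia lists became 0 under scramble and 4 under anti-miR-210 with an estimated correlation. The correlation of the ischemia responses was 0.951 with no background correction and 0.874 with median scaling.

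With each array left out in turn, gene counts ranged from 6982 to 7252 and 6833 to 7409 for ischemia under scramble and anti-miR-210, 17 to 1201 for the oligonucleotides in ischemic and 1 to 2 in non-ischemic muscle, 1 to 61 for the interaction, and 188 to 587 and 351 to 948 against untreated muscle. List counts ranged from 15 to 17, 14 to 15, 3 to 7, 0 to 2, 2 to 6 and 0 to 2 in that order, the last for scramble against untreated. The correlation ranged from 0.920 to 0.951. Some of the arrays behind these ranges are named with the comparisons. The counts of 587 and 948 were both without untreated replicate 1. The correlation was 0.920 without ischemic anti-miR-210 replicate 4 and 0.951 without replicate 3.

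The replicate number as a block gave 7516, 7393, 134, 1 and 0 genes for ischemia under each oligonucleotide, the oligonucleotides in ischemic and non-ischemic muscle and the interaction, and 337 and 709 against untreated muscle. It gave 1 list for the oligonucleotides in non-ischemic muscle and 1 for scramble against untreated, and moved no other count by more than 1.5 times. Same-numbered arrays deviated together weakly (r 0.0486 to 0.169 under scramble, 0.0871 to 0.237 under anti-miR-210), and 8 of 8 and 7 of 8 arrays correlated best with their own number across ischemia, a hint from the data and not from the design. Across oligonucleotides 2 of 8 ischemic and 1 of 8 non-ischemic arrays did so. The block joined equal numbers of all groups, so a pairing within each oligonucleotide was not fitted. A chip block and the seed-site test were not run.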

Other observations

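The splits of this part were planned, and sorting them by how they mix the groups, Rn18s and the kidney and clock lists were chosen only after the result was seen. Rn18s, an 18S ribosomal RNA probe, was 10.78 to 11.07 (log2) on the untreated arrays, 12.95 to 13.69 and 13.06 to 13.82 on the non-ischemic scramble and anti-miR-210 arrays, and 12.21 to 12.84 and 13.04 to 13.64 on the ischemic ones, so it parts the ischemic groups of the 157 genes and of the 4 shifted lists as brightness does. Whether RNA quality differed between these groups was not tested. None of the 3 measured kidney tubule genes passed in a comparison with untreated muscle, over all genes or adjusted over the list alone. Of the clock genes, 1 of 3 positive-arm members rose under either oligonucleotide against untreated muscle (1 and 2 adjusted over the list alone), and 1 and 2 of 10 negative-arm members fell (2 and 2 adjusted over the list alone).

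Other splits of the same arrays were compared with the real one. For ischemia only the real split gave as many genes, under scramble (1 of 35 splits as large, real 7549, highest other 0) and under anti-miR-210 (1 of 35, real 7447, highest other 805). The same held against untreated muscle, for scramble (1 of 35, real 422, highest other 165) and anti-miR-210 (1 of 35, real 839, highest other 21). This argues against chance only if the arrays are exchangeable, which the weak likeness of same-numbered arrays across ischemia leaves uncertain. It is the smallest share that 35 splits allow, and it was not adjusted over the counts tested. Chance cannot be excluded for the 157 genes between oligonucleotides in ischemic muscle (3 of 35 splits as large, highest other 1271), the 1 gene in non-ischemic muscle (2 of 35, highest other 1) or the 3 genes of the interaction (8 of 100 splits, highest other 156). The splits of the non-ischemic arrays weigh the count alone and leave aside the lower level of Ap1b1 with anti-miR-210 in ischemic muscle. The split with 1271 genes set ischemic scramble replicates 1, 3 and 4 and ischemic anti-miR-210 replicate 4 against the other arrays, which differed in brightness by -0.64 (log2), and the same split gave the 156. That split keeps 3 of 4 arrays of each ischemic group together, and so part of the difference between the oligonucleotides. Of 16 such splits 2 gave as many as the 157 genes, and of the 18 that mix the groups evenly 0 did (highest 63). What sets the arrays of the largest split apart was not tested.

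Chance cannot be excluded for the counts of shifted lists between the oligonucleotides in ischemic muscle, in the interaction or for scramble against untreated muscle, and the splits leave it open for ischemia. The count of 0 in non-ischemic muscle cannot be tested this way, since every split gives at least 0. The 1 list of anti-miR-210 against untreated muscle was not tested this way. As large a count was given by 2 of 35 splits for ischemia under scramble (real 16, highest other 18), 18 of 35 under anti-miR-210 (real 14, highest other 17), 29 of 35 for the oligonucleotides in ischemic muscle (real 4, highest other 17), 35 of 35 in non-ischemic muscle (real 0, highest other 6), 81 of 100 for the interaction (real 3, highest other 17) and 19 of 35 for scramble against untreated (real 2, highest other 8). For ischemia these counts say little about chance, since splits that keep 3 of 4 arrays of a group together keep part of the ischemia difference: 1 of 16 such splits gave as large a count under scramble and 16 of 16 under anti-miR-210. Of the 18 splits that mix the groups evenly, 0 did so under scramble (highest 6) and 1 under anti-miR-210 (highest 14).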
